A study of Mus musculus with 16 samples.

How the data were processed

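RNA from alveolar epithelial type II (AT2) cells of mouse pups was measured on 16 single-colour Agilent arrays labelled with Cy3. Per the labels, all pups were 3 days old, were wild type or heterozygous for Fgf10 (Fgf10+/-), and were kept in room air (normoxia) or in a chamber with 85% oxygen from postnatal day 0 to day 3 (hyperoxia). Groups followed the titles and genotype labels, which give 4 wild-type normoxia, 4 Fgf10+/- normoxia, 6 wild-type hyperoxia and 2 Fgf10+/- hyperoxia samples. The series text gives 4 per group instead. The sample labels were followed, and no sample was moved by its values. How the cells were sorted or purified is not given in the sources used here.

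The deposited values were log2 intensities, 1 per array feature and sample, as inferred from their range (-0.4 to 15.98). The sorted values of the 16 arrays differed by at most 0.2 at any position, so the authors' table was already normalized to a shared distribution. The software, the background correction and the log base are not given in the sources used here. No detection flag, slide or scan label came with the values, so features at background could be recognised only by a low value, and slides could not be tested. The median over all values was 4.34. Sftpc, the surfactant protein C gene, lay within 0.05 of the highest value on 16 of 16 arrays and Hba-a1 on 7, so a change of Sftpc was not measurable. For arrays, the number of samples limits the precision.

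The table held 62976 features, of which 65 had a missing value and were left out. In the probe annotation 31465 features had 1 gene symbol, 0 had several, and 31511 had no listed gene. Symbols were updated through RefSeq gene tables of the GRCm38.p6 assembly: 29036 features by accession, 2075 by symbol and 349 by synonym, while 5 kept the listed name. The symbol changed for 3282 features. After features with missing values were dropped, 31439 named features covered 20725 genes. For the 6165 genes with more than 1 feature (at most 13), the feature with the highest mean over all samples stood for the gene. No coordinates were printed, since none came with the deposited values.

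Group means were fitted to the log2 values with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes) on all 16 samples, so that the groups shared 1 estimate of the spread. The contrasts were hyperoxia minus normoxia in each genotype, Fgf10+/- minus wild type in each oxygen condition, and the interaction of genotype and hyperoxia. P-values were adjusted with the Benjamini-Hochberg method over the 20725 genes, and a gene was called at an adjusted p under 0.05. Gene lists were written before the data were examined and tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 33 lists, with the estimated correlation beside it. Of 524 list members written, 503 were measured, and the others were not analysed here.

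The gene lists covered AT2 identity and surfactant, AT1 identity, transitional injured epithelium, p53 targets, NRF2 targets, other antioxidant enzymes and metallothioneins, hypoxia-inducible factor targets and glycolysis, mitosis, DNA replication, cholesterol synthesis, fatty acid and phospholipid synthesis, the FGF receptor signalling response, inflammatory cytokines and chemokines, the interferon response, antigen presentation, the unfolded protein and integrated stress response, oxidative phosphorylation, the circadian clock, the glucocorticoid response, and the immediate early and dissociation response. Cell type lists covered ciliated, club and secretory, basal, neuroendocrine and endothelial cells, fibroblasts, smooth muscle cells and pericytes, macrophages, neutrophils, T and NK cells, B cells and erythroid cells, with sex-linked genes besides.

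Named genes followed a rule set before the data were examined. Per comparison it took the 8 highest and 8 lowest log2 fold changes among called genes whose compared groups did not overlap, with a fold of at least 1.5 and without predicted or clone-named genes. Where fewer than 10 genes were called, it took the 5 smallest p-values in each direction. It added up to 3 called members of each list, or the 2 brightest where none was called, and always Fgf10, Fgfr2, Sftpc, Cdkn1a, Mki67, Nqo1 and Ager. A list of 10 thymocyte markers (Rag1, Rag2, Dntt, Ptcra, Cd8a, Cd8b1, Themis, Ccr9, Arpp21, Tcf7) was added after the data had been seen, when Rag1, Dntt, Cd8a, Ccr9 and Tcf7 had stood out in a regrouping of the normoxia samples.

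The fit was tested on simulated data for the same 20725 genes, with 200 changed genes in each of 5 runs. For hyperoxia in wild type it recovered 37.6% of 2-fold and 90% of 4-fold changes. The figures were 13.2% and 69% for hyperoxia in Fgf10+/-, 31.4% and 84% for genotype in normoxia, 17.8% and 71.8% for genotype in hyperoxia, and 3.6% and 39.4% for the interaction. False calls made up 3.48% to 6.38% of calls. A simulated list of 21 genes shifted by 0.5 was found in 5 of 5 runs for each comparison except the interaction, where it was found in 3. The simulated genes were independent of each other, which the measured genes are not.

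Alternatives set before the data were examined were a further quantile normalization, median centring, leaving out the third of genes with the lowest mean, the mean of all features of a gene, a trended and robust eBayes, array weights, only the groups compared, the replicate number as a block, a sex covariate, all features tested singly, each sample left out in turn, and the genotype ignored. Added after the data had been seen were leaving out co-varying genes, the thymocyte marker mean as a covariate, leaving out the 4 libraries highest in these markers, and an exact two-sided permutation of per-array list means. No label says that samples came from separate animals, so p-values measure only the spread between these samples, which may be technical. Within groups the arrays correlated at 0.941 to 0.973 across features, and 0 pairs held identical values. Tables were made with Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9.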

Results

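Gene expression was measured in AT2 cells, the alveolar cells that make surfactant, from 3-day-old mouse pups. The samples were 4 wild-type and 4 Fgf10+/- libraries from normoxia and 6 wild-type and 2 Fgf10+/- libraries from hyperoxia. Fgf10 is a fibroblast growth factor made by lung mesenchyme, and hyperoxia of newborn mice is used as a model of bronchopulmonary dysplasia. The values are log2 intensities normalized by the authors, and fold changes are differences of group means on that scale. The first principal component held 26.7% of the variance, and all 8 hyperoxia samples lay above all 8 normoxia samples on it. The Fgf10 feature was dim, at 4.74 ± 0.77 in wild-type normoxia (SD, n = 4), 4.42 ± 0.36 in Fgf10+/- normoxia (n = 4), 5.13 ± 0.28 in wild-type hyperoxia (n = 6) and 5.07 ± 0.43 in Fgf10+/- hyperoxia (n = 2), so it does not check the genotype labels.

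Wild-type AT2 samples from 85% oxygen had higher levels of 3 p53-induced genes. They had lower levels of single genes from the antigen presentation, inflammatory and hypoxia-inducible factor lists. Aen, a p53-induced exonuclease, was 2.65-fold higher, at 10.21 ± 0.19 (SD, n = 6) in hyperoxia and 8.80 ± 0.32 (n = 4) in normoxia. Cd74, the invariant chain of MHC class II, was 2.97-fold lower, at 9.15 ± 0.43 (n = 6) against 10.72 ± 0.35 (n = 4). Dlk1, a Notch-related transmembrane protein, was 3.92-fold lower, at 9.44 ± 0.39 (n = 6) against 11.41 ± 0.35 (n = 4). In each of these genes the 6 hyperoxia samples did not overlap the 4 normoxia samples, which the naming rule required of Cd74 and Dlk1.

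Of the 20725 genes, 367 rose and 282 fell with hyperoxia in wild type by limma with Benjamini-Hochberg adjustment, 649 in all, and 3774 had an unadjusted p under 0.05. Median centring gave 509 higher and 161 lower genes, because it moved the median change of all genes from -0.08 to 0.03, a shift of 0.12 that applies to every value given here. The count was 323 without wild-type normoxia replicate 2, 381 without replicate 4, and 278 without the 4 libraries highest in thymocyte markers, of which 1 (replicate 4) belonged to this comparison. With the thymocyte marker mean as a covariate the count was 423, of which 345 were among the 649.

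The p53 list held 24 measured members, of which 17 had a positive change and 3 rose (7 adjusted over the list alone). Aen changed by 1.41 on the log2 scale (SE 0.19, limma with Benjamini-Hochberg adjusted p = 5.26e-04), the cyclin G gene Ccng1 by 1.34 (adjusted p = 0.00255) and Phlda3, an inhibitor of AKT signalling, by 1.68 (adjusted p = 0.00284). A second Aen feature changed by 1.34. Cdkn1a, the p21 gene, changed by -0.24 (limma adjusted p = 0.493). The list median was 0.26 (camera FDR = 3.78e-04, adjusted p = 0.273 with an estimated correlation, not past 0.05).

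Antigen presentation had a lower median. Of 13 members 12 had a negative change and 4 fell (7 adjusted over the list alone), among them H2-Ab1, an MHC class II chain (-1.22, limma with Benjamini-Hochberg adjusted p = 9.92e-04), Cd74 (-1.57, adjusted p = 0.00448) and the class I gene H2-D1 (-1.24, adjusted p = 0.0113, not past 0.05 without wild-type normoxia replicate 2, where it was -1.17). The list median was -0.69 (camera FDR = 1.84e-05, adjusted p = 0.189 with an estimated correlation, not past 0.05). In an exact two-sided permutation of per-array list means over 210 splits this list and the unfolded protein list reached p = 0.00476, the smallest these splits can give, and p53 targets and hypoxia-inducible factor targets p = 0.00952. None of the 33 lists passed Benjamini-Hochberg adjustment there (smallest adjusted permutation p = 0.0785).

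Among hypoxia-inducible factor targets, 3 of 23 fell (5 adjusted over the list alone): the carbonic anhydrase Car9 (-1.26, limma with Benjamini-Hochberg adjusted p = 0.0172), Ndrg1 (-1.21, adjusted p = 0.0211) and the phosphofructokinase Pfkl (-0.86, adjusted p = 0.0235). Without wild-type normoxia replicate 2 these were -1.13, -1.06 and -0.78 and no longer passed, nor did Ndrg1 without replicate 4 (-1.05) or Pfkl without replicate 3 (-0.72). The list median was -0.21 (camera FDR = 0.00443, adjusted p = 0.525 with an estimated correlation). Of 20 inflammatory genes 3 fell (3 adjusted over the list alone): the neutrophil chemokine Cxcl1 (-1.65, limma with Benjamini-Hochberg adjusted p = 0.0039), Tnfaip3, the A20 inhibitor of NF-kB (-1.13, adjusted p = 0.00117), and Nfkbia (-0.70, adjusted p = 0.0407, lost in 8 of the 10 fits that left out 1 sample, with -0.54 without normoxia replicate 3). The list median was -0.36 (camera FDR = 0.0407, adjusted p = 0.539 with an estimated correlation).

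Other lists past the preset test had lower medians in hyperoxia, and each was lost with an estimated correlation. Cholesterol synthesis had a median of -0.42 (camera FDR = 7.49e-04, adjusted p = 0.525 with an estimated correlation), and of its 16 members the sterol carrier Stard4 fell (-1.01, limma with Benjamini-Hochberg adjusted p = 0.00549), as did Mvd (-0.80, adjusted p = 0.0472). The Mvd call was lost in 9 of the 10 fits that left out 1 sample, and Stard4 did not pass with the mean of all its features (limma adjusted p = 0.287). Across the 15 members of the unfolded protein and integrated stress response the median was -0.42 (camera FDR = 0.00255, adjusted p = 0.273 with an estimated correlation), and Chac1, a glutathione-degrading enzyme, fell by 1.66 (limma adjusted p = 0.0159). Chac1 was -1.54 without normoxia replicate 2 and -1.51 without replicate 4, past 0.05 in neither. The glucocorticoid response had a median of -0.39 (FDR = 0.0376, adjusted p = 0.525 with an estimated correlation), the immediate early response -0.38 (FDR = 0.0213, adjusted p = 0.587), with Ier3 lower by -0.91 (limma adjusted p = 0.0188), and fatty acid and phospholipid synthesis -0.31 (FDR = 0.0498, adjusted p = 0.587 with an estimated correlation). Ier3 was -0.78 without normoxia replicate 2 and -0.86 without replicate 3, past 0.05 in neither.

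Proliferation genes were lower on average. The mitosis list had a median of -0.92 with 22 of 23 members negative (camera FDR = 5.03e-07, adjusted p = 0.525 with an estimated correlation), but only the kinesin Kif23 passed over all genes (-1.12, limma with Benjamini-Hochberg adjusted p = 0.0183), against 12 adjusted over the list alone. Kif23 was lost without normoxia replicate 1 (-1.02), 2 (-1.14) or 4 (-1.06), and the cell division gene Cdca3 (-1.68, adjusted p = 0.0128 by limma) without replicate 4 (-1.33). Mki67, the Ki-67 gene, changed by -0.92 (limma adjusted p = 0.245). DNA replication had a median of -0.66 (camera FDR = 6.06e-05, adjusted p = 0.587 with an estimated correlation) and T and NK cell markers -1.23 (camera FDR = 0.0407, adjusted p = 0.587), with 0 members called by limma in either and 13 and 2 at an unadjusted p under 0.05. The mean of the 10 thymocyte markers was 6.43 in wild-type normoxia replicate 4, 4.47 to 4.75 in the other 3 normoxia libraries and 4.01 to 4.42 in the 6 hyperoxia libraries. Without replicate 4 DNA replication had a median of -0.37 and T and NK cells -0.67.

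NRF2 targets, the oxidative stress response, had 20 of 25 members positive and a median of 0.36 (camera FDR = 4.83e-04, adjusted p = 0.587 with an estimated correlation). By limma 0 members passed and 6 had an unadjusted p under 0.05, with Ephx1 at 1.09 (adjusted p = 0.166) and Nqo1 at 0.30 (adjusted p = 0.669). Markers of other cells also differed. Endothelial markers had a median of 0.46 with 13 of 14 positive (FDR = 7.49e-04, adjusted p = 0.587 with an estimated correlation), fibroblasts 0.42 (FDR = 0.00663, adjusted p = 0.587), smooth muscle cells and pericytes 0.59 (FDR = 0.0162, adjusted p = 0.587), erythroid cells 0.64 (FDR = 0.0238, adjusted p = 0.587), ciliated cells -0.66 (FDR = 0.0397, adjusted p = 0.638) and club and secretory cells -0.67 (FDR = 0.0498, adjusted p = 0.638). Wild-type normoxia replicate 1 stood apart, with a smooth muscle list mean of 8.87 against 6.23 to 6.65 in the other 3, and without it the smooth muscle median was 1.12 and the fibroblast median 0.91. Without replicate 4 they were 0.37 and 0.13, the erythroid median was 0.11, and none of these 3 passed. Of the 19 lists past the preset test in wild type, 9 stayed past it with each sample left out.

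The remaining lists did not pass in wild type. Their medians were -0.35 for AT2 identity, -0.11 for AT1 identity, -0.43 for transitional epithelium, 0.05 for other antioxidants, -0.08 for the FGF response, 0.01 for interferon, -0.06 for oxidative phosphorylation and -0.43 for the clock. Cell type lists gave -0.50 for basal, -0.42 for neuroendocrine, 0.15 for macrophage, 0.10 for neutrophil, -0.25 for B cell and 0.15 for sex-linked genes. Within them Dlk1 fell (-1.97, limma with Benjamini-Hochberg adjusted p = 0.00121, a second feature -2.00), the chemokine Cxcl10 fell (-1.30, adjusted p = 0.00549) and the catalase gene Cat rose (1.47, adjusted p = 0.00964), while a second Cat feature changed by -0.27. Csf3r, the G-CSF receptor, rose (1.56, adjusted p = 0.00775), and the clock gene Bhlhe41 was 0.88 lower with a call lost in 8 of the 10 fits that left out 1 sample. Ager, an AT1 marker, changed by -0.23 (limma adjusted p = 0.74).

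The 8 highest named genes rose together. Hsd3b2, a steroid dehydrogenase, was 19.4-fold higher, at 12.96 ± 0.95 (SD, n = 6) against 8.68 ± 0.23 (n = 4), with a log2 fold change of 4.28 (SE 0.39, limma with Benjamini-Hochberg adjusted p = 3.36e-05). Marchf1, Pign, Klra1, Fgf23, Idua, Mcidas and Snap25 changed by 4.22 to 3.90. Over the alternatives other than leaving out 1 sample, Hsd3b2 changed by 1.37 to 4.40 and Marchf1 by 0.48 to 4.33. With the mean of all features of a gene Marchf1 did not pass (limma adjusted p = 0.0902). Snap25, which has 1 feature, stayed at 3.70 to 4.01 over these alternatives. The 8 features, chosen for their rise, correlated with each other at 0.958 or more over the 16 arrays, a value that the shared rise itself increases. The chosen features of 59 genes, most of the 8 included, followed the mean of the 8 within groups with r over 0.9. Of these 59, 50 rose in wild type, with a median of 2.87, whereas 77 other features of 42 of the same genes had a median of 0.01. Most of these other features were dim and could show little change, and the 14 with a mean over 6 had a median of 0.41. Within-group r with that mean was 0.84 for Hsd3b2, which is therefore not among the 59, 0.86 for Cat and 0.81 for Csf3r, against 0.02 for Aen, 0.35 for Phlda3 and -0.61 for Ccng1. Without the 59 genes 550 were called in wild type, and 333 without the 419 genes at r over 0.7, alternatives added after the data had been seen.

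The lowest changes among called genes in wild type, besides those above, were those of Ralgps1, a guanine nucleotide exchange factor for Ral (-1.69, limma with Benjamini-Hochberg adjusted p = 6.61e-04), Itih4, an acute-phase protein (-1.62, adjusted p = 0.0188), and Vwa3b (-1.58, adjusted p = 0.00117). Itih4 was -1.35 without normoxia replicate 1 and -1.61 without replicate 2, past 0.05 in neither. Of the 34 named genes past the threshold in wild type, 22 stayed past it with each sample left out.

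In Fgf10+/- AT2 samples antigen presentation and interferon-response genes fell with hyperoxia, as did single genes such as Cfb and Lrg1. Cfb, complement factor B, was 20.9-fold lower, at 6.73 ± 0.91 (SD, n = 2) against 11.11 ± 0.79 (n = 4), and Lrg1, an acute-phase glycoprotein, was 10.2-fold lower, at 6.81 ± 0.94 (n = 2) against 10.16 ± 0.79 (n = 4). H2-Ab1 was 6.21-fold lower, at 7.95 ± 0.29 (n = 2) against 10.59 ± 0.11 (n = 4). Oas1a, an interferon-induced oligoadenylate synthetase, was 8.83-fold lower, at 5.09 ± 0.05 (n = 2) against 8.23 ± 0.66 (n = 4), a lower bound where the hyperoxia value is at background.

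By limma with Benjamini-Hochberg adjustment 245 genes rose and 262 fell in Fgf10+/-, 507 in all, and 3462 had an unadjusted p under 0.05. Median centring gave 270 higher and 167 lower genes, and a fit of only these 2 groups 192 and 69, so the balance of directions depends on the processing. The count rested on 2 hyperoxia samples: it was 90 without the first and 108 without the second, where the remaining sample is assumed to vary like the other groups, and 252 and 278 without normoxia replicates 1 and 4. With the thymocyte marker covariate it was 115, and 14 without the 4 libraries highest in these markers, which leaves 1 Fgf10+/- normoxia library. Of the 37 named genes past the threshold, 10 stayed past it with each sample left out: Hsd3b2, Marchf1, Cfb, Itih4, Lrg1, Cd74, Dlk1, Oas1a, H2-Ab1 and H2-Eb1.

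The lowest changes were those of Saa3, Cfb, Lcn2, Saa1, Itih4 and Lrg1, of which Saa3 and Lcn2 were members of the inflammatory list. Saa3, serum amyloid A3, changed by -5.01 (SE 1.04, limma with Benjamini-Hochberg adjusted p = 0.0208), Cfb by -4.38 (SE 0.59, adjusted p = 0.00233), Lcn2, the iron-sequestering lipocalin 2, by -3.57 (adjusted p = 0.00499), Saa1 by -3.52 (adjusted p = 0.0174), Itih4 by -3.41 and Lrg1 by -3.35 (both adjusted p = 0.0027). Chad, a cartilage matrix protein, changed by -3.21 (limma adjusted p = 0.0262). Without hyperoxia replicate 1 the changes of Saa3, Saa1 and Chad were -4.46, -3.32 and -2.85, without replicate 2 those of Saa3, Lcn2, Saa1 and Chad were -5.56, -2.62, -3.72 and -3.57, and none of these passed. Of 20 inflammatory genes 5 fell (7 adjusted over the list alone), among them Tnfaip3 (-1.35, adjusted p = 0.00649 by limma) and Cxcl1 (-2.07, adjusted p = 0.0119), both lost without hyperoxia replicate 1 at -1.17 and -1.52. The list median was -0.30 (camera FDR = 9.97e-04, adjusted p = 0.241 with an estimated correlation).

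Antigen presentation and the interferon response fell as lists, and both stayed past an FDR of 0.05 with an estimated correlation. Of 13 antigen presentation genes 9 fell (12 adjusted over the list alone), led by Cd74 (-3.22, SE 0.37, limma with Benjamini-Hochberg adjusted p = 7.23e-04), H2-Ab1 (-2.64, adjusted p = 6.52e-05) and H2-Eb1 (-2.40, adjusted p = 0.0027), with a list median of -1.63 (camera FDR = 2.56e-14, and 0.00413 with an estimated correlation). Of 21 interferon genes 5 fell (8 adjusted over the list alone), led by Oas1a (-3.14, limma adjusted p = 0.00214), Cxcl10 (-2.17, adjusted p = 0.00328) and Oasl2 (-1.71, adjusted p = 0.00513), with a median of -0.75 (camera FDR = 3.43e-06, and 0.0172 with an estimated correlation). Cxcl10 and Oasl2 were -1.68 and -1.60 without hyperoxia replicate 1 and did not pass. With 2 samples against 4 an exact permutation cannot reach 0.05.

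The p53 list had 5 members higher in Fgf10+/- hyperoxia (6 adjusted over the list alone), among them Phlda3 (2.40, limma with Benjamini-Hochberg adjusted p = 0.00457), Ccng1 (2.83-fold, adjusted p = 0.0168) and Aen (1.27, adjusted p = 0.0174). The median was 0.24 (camera FDR = 0.0104, adjusted p = 0.341 with an estimated correlation), and 0.08 without hyperoxia replicate 2, past 0.05 no longer. On the log2 scale Phlda3 was 2.10 without replicate 2, Ccng1 1.70 and 1.30 and Aen 1.36 and 1.19 without the first and the second, none past 0.05. Of 23 hypoxia-inducible factor targets 3 fell (5 adjusted over the list alone): Ndrg1 (-1.82, limma adjusted p = 0.0174), Pfkl (-1.33, adjusted p = 0.0168) and Ddit4, an inhibitor of mTORC1 signalling (-1.99, adjusted p = 0.0412). Without hyperoxia replicate 1 they were -1.45, -1.36 and -2.16 and did not pass. Their list median was -0.35 (camera FDR = 0.00499, adjusted p = 0.341 with an estimated correlation).

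The mitosis list had a median of -1.50 with 22 of 23 members negative (camera FDR = 3.68e-12, adjusted p = 0.341 with an estimated correlation). Over all genes only the spindle gene Prc1 fell (-1.73, limma with Benjamini-Hochberg adjusted p = 0.0402), against 19 adjusted over the list alone, and Prc1 was lost without either hyperoxia sample, at -1.47 and -1.98. DNA replication had a median of -0.79 (camera FDR = 1.35e-05, adjusted p = 0.551 with an estimated correlation), with 0 members past limma and 11 at an unadjusted p under 0.05. The thymocyte marker mean was 5.74, 6.38, 4.25 and 5.54 in Fgf10+/- normoxia replicates 1 to 4 and 4.31 and 4.28 in the hyperoxia samples. With it as a covariate the mitosis median was -0.83 and the DNA replication median -0.01.

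Endothelial markers were higher on average in Fgf10+/- hyperoxia, with a median of 1.14 and 12 of 14 positive (camera FDR = 5.09e-07, adjusted p = 0.355 with an estimated correlation). Egfl7 (2.46, limma with Benjamini-Hochberg adjusted p = 0.00714), the tight junction gene Cldn5 (2.08, adjusted p = 0.0174) and Ramp2 (1.71, adjusted p = 0.0421) passed, 6 adjusted over the list alone. Without hyperoxia replicate 2 the list median was 0.59, still past 0.05, and Egfl7, Cldn5 and Ramp2 were 1.88, 1.46 and 1.01, none past 0.05. Smooth muscle and pericyte markers had a median of 1.05 (camera FDR = 0.00633, adjusted p = 0.551 with an estimated correlation), macrophages 0.30 (FDR = 0.0267, adjusted p = 0.551), club cells -1.18 with 0 of 8 positive (FDR = 0.0221, adjusted p = 0.651), NRF2 targets 0.51 (FDR = 0.00185, adjusted p = 0.551), the unfolded protein response -0.40 (FDR = 0.0221, adjusted p = 0.341) and AT2 identity -0.43 (FDR = 0.0161, adjusted p = 0.682). Within AT2 identity Dlk1 fell by 2.98 (limma adjusted p = 0.00233), and the list median was 0.06 without hyperoxia replicate 2. The NRF2 list mean was 8.66 and 9.06 in Fgf10+/- hyperoxia replicates 1 and 2 and 8.12 to 8.62 in Fgf10+/- normoxia.

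Hsd3b2 again had the highest change among named genes in Fgf10+/-, at 4.46 (SE 0.52, limma with Benjamini-Hochberg adjusted p = 7.23e-04), and of the co-varying genes Pign, Marchf1, Snap25, Fgf23 and Idua changed by 3.89 to 3.55. Of the 59 co-varying genes 39 rose, with a median of 2.57. Adh1, an alcohol dehydrogenase, changed by 3.93 (adjusted p = 0.0445 by limma) and Stard9 by 3.76 (adjusted p = 0.00328), with a within-group r to that mean of 0.46 and 0.77. Adh1 was 4.37 and 3.49 without the first and the second hyperoxia sample, past 0.05 in neither. Cat (1.57, limma adjusted p = 0.0446) and the fibroblast gene Inmt (2.35, adjusted p = 0.0441) lost their calls without any 1 of the 6 samples, with values down to 1.09 for Cat and 1.60 for Inmt.

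The responses of the genotypes overlapped, with no library shared between these comparisons, though both used the same estimate of the spread. Without slide or scan labels, an array batch that followed oxygen cannot be told apart from hyperoxia in either comparison or in their overlap. Of the genes that rose, 172 rose in both, and of those that fell, 106 fell in both, where independent lists of these sizes would share 3.56. By limma 0 genes rose in one and fell in the other. Outside the 59 co-varying genes, 133 rose in both, and 592 of the 599 genes called in wild type had the same sign in Fgf10+/-. Across all genes, which are not independent replicates, the fold changes correlated with a Pearson r of 0.63 and a Spearman rho of 0.51.

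**Figure D1:**
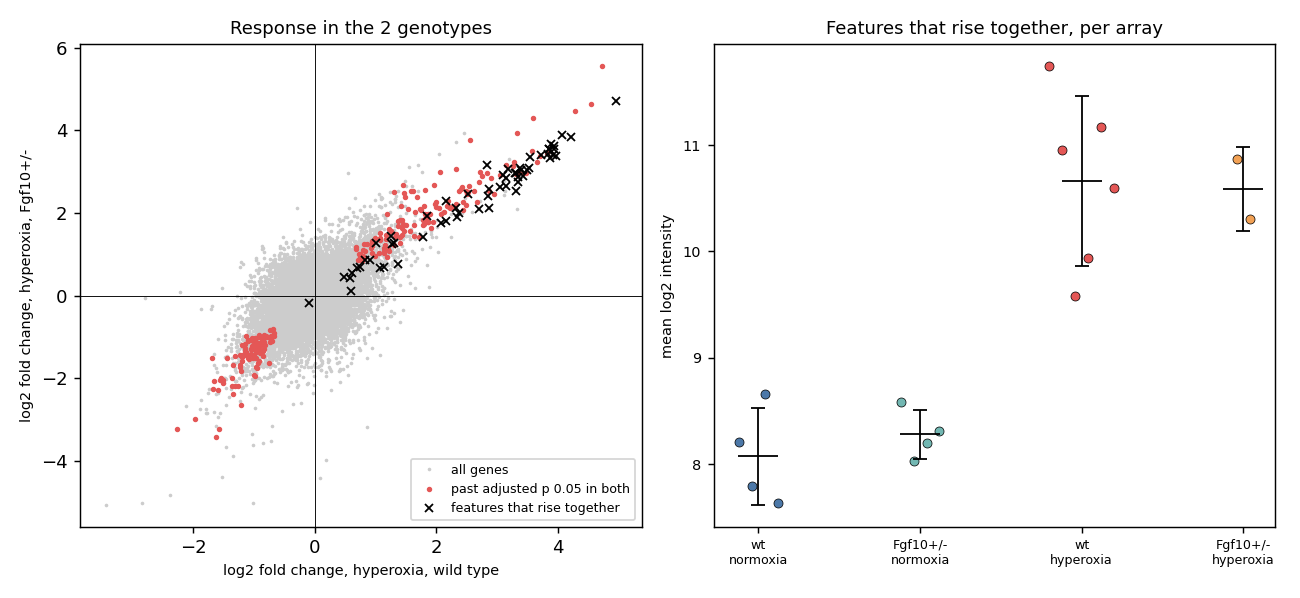
Left, log2 fold changes with hyperoxia in wild type (horizontal) and in Fgf10+/- (vertical) for all genes, with genes past adjusted p 0.05 in both marked as red points and the 59 co-varying genes as crosses. Right, the mean log2 intensity of these 59 genes on each array, with the group mean (bar) and SD (error bar); the wild-type hyperoxia arrays lie between 9.59 and 11.74 and the wild-type normoxia arrays between 7.64 and 8.66.

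In normoxia, Fgf10+/- AT2 samples had higher interferon-response genes than wild type. Oasl2, an interferon-induced antiviral gene, was 3.01-fold higher, at 8.40 ± 0.34 (SD, n = 4) against 6.81 ± 0.30 (n = 4), and Lrg1 was 6-fold higher, at 10.16 ± 0.79 (n = 4) against 7.58 ± 0.49 (n = 4). The mean of the 21 interferon genes was 7.01 to 7.34 on the Fgf10+/- arrays and 6.43 to 6.59 on the wild-type arrays. In hyperoxia it was 6.30 to 6.53 in wild type and 6.30 to 6.38 in Fgf10+/-.

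These 2 genes were the only ones past an adjusted p of 0.05 by limma with Benjamini-Hochberg adjustment (Oasl2 1.59, SE 0.22, Lrg1 2.59, SE 0.38, adjusted p = 0.0421 for both, higher in 4 of 4 samples). An unadjusted p under 0.05 was reached by 1250 genes, not far above the 0.05 of 20725 that chance alone would give. The calls of Oasl2 and Lrg1 were weak. Both genes were lost without Fgf10+/- normoxia replicate 1, 3 or 4 or wild-type normoxia replicate 1, 2 or 4, with values of 1.51 to 1.57 for Oasl2 and 2.38 to 2.80 for Lrg1, and Lrg1 also without wild-type replicate 3 (2.55).

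The interferon list had a median of 0.66 with 20 of 21 members positive (1 past limma over all genes, 7 adjusted over the list alone). Its camera FDR was 2.99e-15, and 4.37e-04 with an estimated correlation. Antigen presentation had a median of 0.41 with 11 of 13 positive (FDR = 3.8e-04, adjusted p = 0.28 with an estimated correlation). By limma 0 antigen presentation genes passed and 3 had an unadjusted p under 0.05, with H2-K1 at 0.69 (adjusted p = 0.732). In an exact two-sided permutation of list means over 70 splits, interferon and endothelial markers reached p = 0.0286, the smallest these splits can give, with a Benjamini-Hochberg adjusted permutation p = 0.471 over 33 lists.

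Endothelial markers were lower in Fgf10+/- normoxia, with 0 of 14 positive and a median of -0.74 (camera FDR = 4.61e-07, adjusted p = 0.449 with an estimated correlation). Egfl7 changed by -1.03 (limma adjusted p = 0.618) and Cldn5 by -1.13 (adjusted p = 0.541). Smooth muscle and pericyte markers had a median of -0.86 (FDR = 4.25e-04, adjusted p = 0.573 with an estimated correlation), but -0.28 without wild-type normoxia replicate 1, not past 0.05. With the adjusted p again from an estimated correlation, macrophages had -0.64 (camera FDR = 6.88e-06, adjusted p = 0.335), neutrophils -0.35 (FDR = 0.0255, adjusted p = 0.573) and B cells -0.83 (FDR = 0.00699, adjusted p = 0.449). AT1 identity had a median of 0.39 with 19 of 19 positive (camera FDR = 1.08e-05, adjusted p = 0.573 with an estimated correlation), the immediate early response -0.32 (FDR = 0.00474, adjusted p = 0.818), mitosis 0.34 (FDR = 0.00351, adjusted p = 0.869) and DNA replication 0.28 (FDR = 0.00474, adjusted p = 0.888). The thymocyte markers had a median of 0.36, and without the 4 libraries highest in them mitosis and DNA replication had medians of -0.07 and -0.20. Of the 11 lists past the preset test between genotypes in normoxia, 5 stayed past it with each sample left out.

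Other genes with the smallest p-values did not pass. Timp1, an inhibitor of metalloproteinases (2.20), the apolipoprotein gene Apol9a (1.59) and Slpi, a secreted protease inhibitor (2.11), were higher and Gdf15, a stress-induced cytokine (-1.51), was lower, each with a limma Benjamini-Hochberg adjusted p = 0.0952. The chemokine Ccl6 changed by -2.60 (adjusted p = 0.107 by limma), the eosinophil-associated ribonuclease Ear2 by -2.62 (adjusted p = 0.108), Hexim1 by -1.12 (adjusted p = 0.108) and the mast cell and basophil protease Prss34 by -1.73 (adjusted p = 0.141). Fgf10 itself changed by -0.32 (limma adjusted p = 0.961), its receptor Fgfr2 by 0.08 (adjusted p = 0.986) and Etv5, a target of FGF signalling, by -0.52 (adjusted p = 0.86). The FGF response list had a median of -0.13 with 5 of 15 positive and did not pass (FDR = 0.467).

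**Figure D2:**
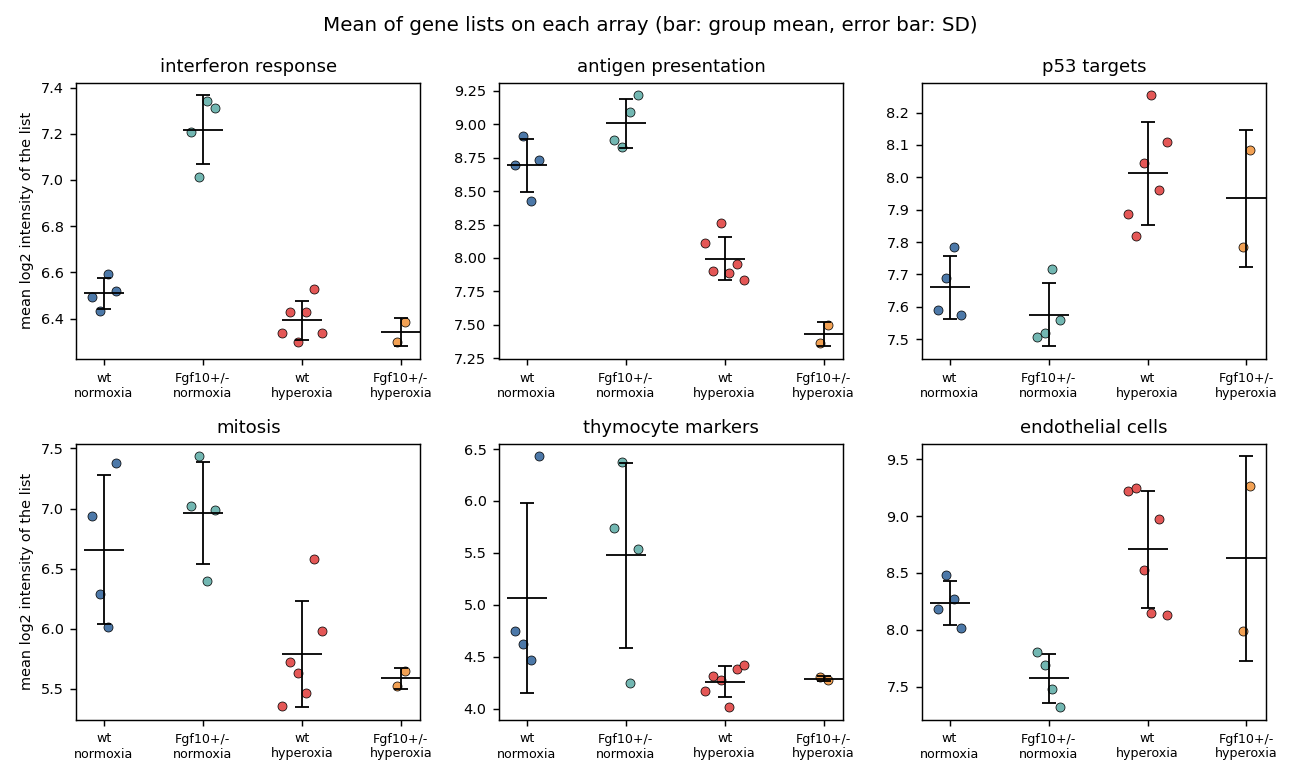
Mean log2 intensity of 6 gene lists (vertical) on each array of the 4 groups (horizontal), with the group mean (bar) and SD (error bar). The 4 Fgf10+/- normoxia arrays lie between 7.01 and 7.34 for the interferon response, above all other arrays; antigen presentation lies between 8.43 and 9.22 in normoxia and between 7.37 and 8.26 in hyperoxia.

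In hyperoxia, 0 genes differed between Fgf10+/- and wild type by limma with Benjamini-Hochberg adjustment (smallest adjusted p = 0.289). An unadjusted p under 0.05 was reached by 906, fewer than the 0.05 of 20725 genes that chance alone would give. Antigen presentation genes had lower values in Fgf10+/-, with 12 of 13 negative and a median of -0.41 (camera FDR = 4.06e-07, adjusted p = 0.0668 with an estimated correlation, not past 0.05, 5 members adjusted over the list alone). H2-K1, a class I gene, was at 11.37 ± 0.10 (SD, n = 2) against 11.70 ± 0.17 (n = 6), a change of -0.33. The list mean was 7.37 and 7.50 in the Fgf10+/- samples and 7.84 to 8.26 in wild type.

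The genes with the smallest p were Colca2 (-1.79, limma adjusted p = 0.289), the olfactory receptor genes Olfr58 (-1.75) and Olfr692 (1.16), the complement protease gene C1rb (-1.32) and Ms4a6c (-1.84), each of the last 4 with an adjusted p = 0.31. The beta-glucan receptor Clec7a (-2.06) and the imprinted gene Snrpn (0.92) had an adjusted p = 0.672 by limma. AT1 identity had a median of 0.58 with 18 of 19 positive (camera FDR = 4.65e-06, adjusted p = 0.673 with an estimated correlation), and 0.02 without Fgf10+/- hyperoxia replicate 1. AT2 identity had -0.30 (camera FDR = 0.00799, adjusted p = 0.873 with an estimated correlation), and 0.32, past 0.05 in the other direction, without replicate 2. Emp2, an AT1 membrane protein, changed by 0.63 and Ear2 by -1.87 (limma adjusted p = 0.938). Transitional epithelium had 0.35 (FDR = 0.0298, adjusted p = 0.873), cholesterol synthesis 0.22 (FDR = 0.00221, adjusted p = 0.673), inflammatory genes -0.21 (FDR = 0.0117, adjusted p = 0.621), the immediate early response -0.27 (FDR = 0.0163, adjusted p = 0.873), macrophages -0.49 (FDR = 0.00221, adjusted p = 0.673) and neutrophils -0.60 (FDR = 0.00221, adjusted p = 0.621), each adjusted p with an estimated correlation. Of these lists 2, antigen presentation and neutrophils, stayed past 0.05 with each sample left out.

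The interaction asked whether the response to hyperoxia differed between genotypes. Camera found a difference for the interferon list, with a median of -0.76 and 17 of 21 negative. It found another for antigen presentation, with -0.89 and 12 of 13 negative. Both rest on 2 Fgf10+/- hyperoxia samples, and no regrouping or permutation was run for the interaction. In these 2 samples the mean of 3 Y-linked genes lay below Xist, by -1.22 and -0.73, while each other group held both signs. These features were dim, so a sex difference between the groups is neither shown nor excluded. The interferon list had a median of -0.75 with hyperoxia in Fgf10+/- and of 0.01 in wild type, where it did not pass. The mean of the list per array was nonetheless lower in wild-type hyperoxia, by -0.12 (exact permutation p = 0.0571). There 6 members had an unadjusted p under 0.05 by limma. Between the genotypes the interferon list differed in normoxia (0.66) but not in hyperoxia (0.05). Its interaction therefore largely restates the normoxia difference, for which chance cannot be excluded once the choice of list is counted. Camera gave an FDR of 1.45e-09 and 4.9e-11, and 0.00448 and 0.0063 with an estimated correlation. By limma 0 members passed in either list, 8 in each had an unadjusted p under 0.05, and 4 and 3 passed adjusted over the list alone. Without Fgf10+/- hyperoxia replicate 1 the interferon median was -0.46 and still past 0.05.

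In the interaction 852 genes had an unadjusted p under 0.05 by limma, fewer than the 0.05 of 20725 that chance alone would give. With Benjamini-Hochberg adjustment 2 genes passed by limma, C1rb (-2.20, SE 0.33) and the guanine nucleotide exchange factor Psd2 (-2.22, SE 0.33), both with an adjusted p = 0.0471. Both were dim, with group means up to 6.12 for C1rb and 4.12 for Psd2, and each call was lost in 15 of the 16 fits that left out 1 sample. Oasl2 (-1.78), Il18bp, the inhibitor of interleukin 18 (-2.14), and Rprml (-2.09) had a limma adjusted p = 0.551, and Lcn2 (-2.72), Isg15 (-1.73) and H2-K1 (-1.02) did not pass. A further 3 lists passed the preset test: mitosis (-0.54, FDR = 6.18e-04, adjusted p = 0.995 with an estimated correlation), inflammatory genes (-0.24, FDR = 0.033, adjusted p = 0.792) and endothelial markers (0.53, FDR = 0.00197, adjusted p = 0.995), the last 0.11 without Fgf10+/- hyperoxia replicate 2 and not past 0.05. Egfl7 differed by 1.40. Mitosis was -0.29 without wild-type normoxia replicate 3, no longer past 0.05, and thymocyte markers differed by a median of -0.36.

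With an estimated correlation 5 list results stayed under an FDR of 0.05: interferon in Fgf10+/- hyperoxia, in Fgf10+/- normoxia against wild type and in the interaction, and antigen presentation in Fgf10+/- hyperoxia and in the interaction. The 3 interferon results share the same 4 Fgf10+/- normoxia arrays, as do those of antigen presentation, so they are not independent of each other. Random regroupings of the wild-type samples gave up to 19 lists past the preset test, the number found for hyperoxia. Their smallest camera p reached 4e-24, against 1.52e-08 for hyperoxia.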

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

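The tests of shared RNA, other cell types, array batch, leukocytes and thymocytes and the regroupings were chosen after the results were seen, the last with the expected outcome written before they were run, while leaving out 1 sample and testing all features were planned before.

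Features of 59 genes rose together in hyperoxia by a median of 2.87 in wild type, while the other features of these genes with a mean over 6 had a median of 0.408, so the 59 may read a shared RNA and not the genes they are named for. The comparison rests on 14 other features, and it covers neither Snap25 and Mcidas, which have 1 feature each, nor Hsd3b2, which is outside the 59. Hsd3b2 lay outside by its within-group r of 0.84, but its change fell to 1.37 over the alternatives other than leaving out 1 sample. Snap25 stayed at 3.70 or more, so the same question stays open for Hsd3b2. RNA of another listed cell type was expected to rise at least by the lower quartile of the 59, 1.34 in wild type. The highest median among cell type lists with a mean under 10, that of smooth muscle cells and pericytes, was 0.59, with 0.64 for the brighter erythroid list. Wild-type normoxia replicate 1, at 8.87 against 6.23 to 6.65, lowered the smooth muscle change. In Fgf10+/- the endothelial and smooth muscle medians were 1.14 and 1.05, against 2.57 for the 59. RNA of another cell type is therefore not excluded. The lowest hyperoxia array lay 0.93 above the highest normoxia array in the mean of the features of the 59 genes. Without slide or scan labels this gap cannot separate an effect of array batch from one of hyperoxia. Hybridising the same RNA again with normoxia and hyperoxia samples mixed on each slide, or sequencing it, would tell these apart.

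Interferon-response genes were higher in Fgf10+/- normoxia, and no single library carried this, since the median was at least 0.569 with any 1 left out. More macrophages or B cells would raise their markers, but the higher of their medians was -0.636, while thymocyte markers did have a higher median (0.36, 9 of 10 positive), and with these as a covariate the interferon median was 0.57. Among all 35 ways to split the 8 normoxia samples 4 against 4, only 1, the real one, gave a camera p as small (9.06e-17, the next 3.92e-09), but the list was singled out as the strongest of 33. For the smallest camera p of any list, 4 of 35 splits, the real one included, did as well (9.06e-17 real, 3.64e-30 the strongest other), so chance cannot be excluded once that choice is counted. An infection or a litter shared by these 4 samples could give the same values and was not tested, because the labels hold no litter.

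Random regroupings bound the counts as well. For hyperoxia in wild type 2 of 100 groupings, the real one included, gave as many genes (649 real, 693 the highest other), and 3 of 100 gave as many lists (19 real, 19 the highest other). Few other groupings did as well, so chance is unlikely for these counts, but it is not excluded, since neither was above all others. The smallest camera p of any list, however, was 1.52e-08 for the real grouping and smaller in many others, down to 4e-24. Chance can therefore not be excluded for the wild-type list results at the preset correlation. Another split of the same samples, which put wild-type normoxia replicate 1 with hyperoxia replicates 1, 2 and 5, separated even more genes. The rates are approximate, because only 100 of the 210 possible splits were used. They cannot separate hyperoxia from an array batch that followed oxygen. For genotype in normoxia chance cannot be excluded: 2 of 35 gave as many genes (2 real, 79 the highest other) and 11 of 35 as many lists (11 real, 14 the highest other). The split with 79 genes put wild-type normoxia replicate 4 with Fgf10+/- replicates 1, 2 and 4.

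Single samples stood apart from their group by Dixon's ratio, the gap to the nearest sample over the range, in 16 of 247 groups of values, where about 1 in 20 would by chance. In wild-type normoxia these were Mfap4 (14.73 against 10.36 to 11.10, ratio 0.831), Fgf10 (5.89 against 4.27 to 4.50, ratio 0.859) and the smooth muscle and pericyte list (8.87, ratio 0.842) in replicate 1, Isg15 (ratio 0.924) in replicate 2, Csf3r (ratio 0.869) and Oasl2 (ratio 0.841) in replicate 3, and Phlda3 (ratio 0.852) and the cholesterol synthesis list (ratio 0.882) in replicate 4. In Fgf10+/- normoxia they were Fgf23 (ratio 0.839) in replicate 1, Itih4 (ratio 0.873), Dlk1 (ratio 0.856) and Etv5 (ratio 0.855) in replicate 2, the macrophage list (ratio 0.87) in replicate 3 and Timp1 (ratio 0.837) in replicate 4. In wild-type hyperoxia they were Cdca3 (ratio 0.651) in replicate 5 and H2-K1 (ratio 0.655) in replicate 6.

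Responses past the preset tests for a difference between the genotypes were those of C1rb (-2.197), Psd2 (-2.216) and the lists mitosis (-0.542), inflammatory cytokines and chemokines (-0.238), interferon response (-0.759), antigen presentation (-0.891) and endothelial cells (0.53). With an estimated correlation only the interferon and antigen presentation lists stayed past 0.05 (adjusted p = 0.995, 0.792 and 0.995 with an estimated correlation for mitosis, inflammatory and endothelial genes), and the calls of C1rb and Psd2 were each lost in 15 of the 16 fits that left out 1 sample. Of the 31472 tested features without a listed gene, 644 rose and 82 fell with hyperoxia in wild type and 291 rose and 87 fell in Fgf10+/- by limma with Benjamini-Hochberg adjustment. Of the 151 features that followed the co-varying mean with r over 0.9, 86 had no listed gene.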

How the results depend on the processing

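Tests chosen after the results were seen were the removal of co-varying genes, the thymocyte marker covariate, and the removal of the 4 libraries highest in these markers.

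The count for hyperoxia in wild type (649) became 1076 without the dimmest genes, 1000 with trended and robust eBayes, 1330 over all features, 2957 with genotype ignored, 333 without genes co-varying at r over 0.7, 423 with the thymocyte covariate, 278 without the 4 libraries, and 323 to 679 with 1 sample left out. In Fgf10+/- (507) it became 790, 332 with the mean of features, 261 with only the groups compared, 783 over all features, 282, 115, 14, and 90 to 503. Genotype in normoxia (2) gave 8 with trended eBayes, 11 with array weights, 0 with only the groups compared, 0 over all features, 10 without the 4 libraries and 0 to 9 with 1 sample left out. Genotype in hyperoxia (0) gave 2 over all features and 0 to 4 with 1 left out, and the interaction (2) gave 1 without the dimmest genes, 0 with trended eBayes, 0 with a sex covariate, 0 over all features, 0 with the thymocyte covariate, 1 without the 4 libraries and 0 to 3 with 1 left out. Deviations from group means correlated at a mean r of 0.05 over 18 pairs with the same replicate number, against -0.012 for different numbers. The difference was not tested, so pairing by number is neither shown nor excluded. Using replicate numbers as a block gave 216, 103, 0 and 0 for the first 3 comparisons and the interaction. The sign changed, or the change nearly vanished, in wild-type hyperoxia for T and NK cells (-0.036 with the covariate). In Fgf10+/- hyperoxia it did for DNA replication (-0.011 with the covariate, -0.087 without the 4 libraries) and AT2 identity (-0.973 to 0.059 with 1 left out). Between genotypes in normoxia it did for Fgf10 (-0.481 to 0.061), Fgfr2 (-0.018 to 0.197, -0.145 with the mean of features, -0.054 without the 4 libraries), mitosis (-0.072) and DNA replication (-0.2), both without the 4 libraries. In hyperoxia AT2 identity ran from -0.992 to 0.316 between genotypes, and endothelial cells from 0.111 to 1.189 in the interaction, with 1 left out. The cause was not tested.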

Other observations

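The thymocyte tests and the genes and lists compared here were chosen after the results were seen, with the expected outcome of the covariate written before it was run, while leaving out 1 library was planned before.

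Lcn2 and Cfb, chosen after their values had been seen, had their highest group mean in Fgf10+/- normoxia, but neither passed between the genotypes there. Group means of Lcn2 were 11.09 in wild-type normoxia, 12.70 in Fgf10+/- normoxia, 10.24 in wild-type hyperoxia and 9.13 in Fgf10+/- hyperoxia, and those of Cfb were 9.28, 11.11, 7.75 and 6.73. Their falls in Fgf10+/- hyperoxia are measured from that mean. A second set of litters measured for Lcn2, Cfb and Lrg1 would show whether these levels follow genotype or the state of these 4 samples.

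Marker genes of other cells were measured at levels that varied between arrays. The club and secretory list mean ran from 10.82 to 12.79 on wild-type normoxia arrays and from 9.02 to 12.84 on wild-type hyperoxia arrays, and the fibroblast list mean from 7.33 to 9.85 and from 8.08 to 9.26. Changes of endothelial, club, smooth muscle and fibroblast genes therefore cannot be placed in AT2 cells from these data. Which cells the antigen presentation, interferon and inflammatory genes came from was not tested.

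The mitosis list had a lower median in wild-type hyperoxia, lost with an estimated correlation (adjusted p = 0.525 with an estimated correlation). Fewer thymocytes could explain part of it, since with the thymocyte marker mean as a covariate the median was -0.44, against -0.92 without it. The median was -0.691 without the library highest in these markers, so that library alone did not account for the lower median. The marker means of the other 3 normoxia libraries (4.47 to 4.75) lay above those of the 6 hyperoxia libraries (4.01 to 4.42). All these means lay near the median over all values, where few thymocytes cannot be told from background. This gap therefore does not show that thymocytes remained, and how much thymocytes explain stays open. Leaving out any 1 library also left a median of -0.691 or lower, so no single library carried it. Counting dividing SFTPC-positive cells in tissue sections would separate the sources.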
